A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

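Total RNA was measured by sequencing in 8 libraries of *Saccharomyces cerevisiae* W303, 2 each for wild type (WT), 2 strains with SIR3 or its A2Q form under the GPD promoter (GPD-SIR3, GPD-SIR3-A2Q) and a strain lacking SIR3 (sir3Δ), grouped and numbered by their titles. Per the labels' protocols, RNA of exponentially growing cells was extracted with phenol and chloroform, fragmented with zinc, selected by size and made into paired-end SOLiD total RNA libraries. Per the submitters' processing notes, TopHat 1.4.1 and genome build R64 were used. The counting tool, the use of strand and the treatment of reads with several matches are not given in the sources used here, but values of a gene and of a transcript inside it on the other strand show that strands were counted apart.

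The table deposited by the authors lists 11436 features, 5798 of them genes and 5638 non-coding (1658 chunXUT, 1592 XUT, 925 CUT, 847 SUT, 299 tRNA, 219 XUT-A, 77 snoRNA, 15 ncRNA and 6 snRNA). The values of library GPD-SIR3 2 are whole numbers and were read as the authors' counts. The values the authors deposited for the other 7 libraries are a signal, read counts times 1 factor per library, chosen so that genes sum to 7006670 in every library. Dividing by the smallest step recovered whole reads for 100% of values (tolerance 0.01 of a read). From these reads, the depth on genes was 7006670 to 18077542 reads, and 9847370 to 26668086 over all features. snoRNAs took 15.4% to 22.8% of reads and the 10 highest genes 15.6% to 18.0% of gene reads. Another 16 columns of per-sample values in the table were not used. Of the 5798 genes, 5789 matched the reference annotation by systematic name and 5757 had equal coordinates, 93 had no reads in any library, and 23 mitochondrial or plasmid genes have no chromosome end. Coordinates are those of R64, counted from 1.

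The design had called for edgeR if the table held plain counts and limma if it held normalized values. The table is scaled, so limma 3.58.1 (trend) in R 4.3.3 was run on log2(value + 1), with no further scaling, for 5473 genes with a value of at least 10 in at least 2 libraries. All 4 groups entered one model, which left 4 residual degrees of freedom, and calls were made at a Benjamini-Hochberg adjusted p below 0.05, two-sided. Comparisons were each other strain against WT, and GPD-SIR3 against GPD-SIR3-A2Q. The 3093 non-coding transcripts past the same filter were fitted separately. These choices, the gene lists, the distance limit of 30 kb and the rule for named genes were made before the data were examined.

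Genes within 30 kb of a chromosome end were compared with those beyond 50 kb by Fisher's exact test, two-sided and adjusted over the tests made. The 31 gene lists and the distance bins were tested with camera (limma), with a preset correlation of 0.01 and again with an estimated one; lists with fewer than 4 tested members had counts only. Members were also adjusted over the list alone. Shared changes against WT were set beside 100 simulations of unchanged groups with the same controls. Ratios from 1 to 3 reads carry 95% exact intervals, and a group at 0 was given a floor of 3 counts per library, averaged over the group. Replicates of a strain differed by far more than sampling noise (chi-square over degrees of freedom 39.6 in WT, 34.9 in GPD-SIR3, 16.2 in GPD-SIR3-A2Q and 42.6 in sir3Δ), so no pair looked like 1 library deposited under 2 titles, which does not show separate cultures. Each library was treated as a sample. For the closing section, genes within 30 kb were also called duplicated where over 10% of their 50-base stretches lie elsewhere in the genome, a step added after the data were seen.

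Genes were named by a rule: SIR3 first, then SIR1, SIR2, SIR4 and the silent-cassette and MAT genes whatever their values. In each comparison, the 10 higher and 10 lower called genes with the largest changes followed, among those with a mean of at least 10 and groups that do not overlap. Up to 4 called members per list, at most 2 members of lists without a call, and the called gene within 30 kb farthest from its end were added. One gene that the rule names is not reported here. Other genes were chosen after their values were seen. These are IRC7, ZRT1, DLD3, ADH4 and IMD2 in GPD-SIR3 against WT, the genes of the chromosome III end, remaining called members of a list or of a short count, BSC5, TEC1, OPI3, YGL193C, the sulfur and nitrogen genes, and the genes given as examples in the closing section.

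The limma step was tested on simulated data with 200 planted changes per comparison, leaving out the top 5% of genes. Of planted changes of 1.5, 2, 4 and 8-fold, 18%, 66%, 96% and 100% were recovered for GPD-SIR3 against WT (5458 genes), and 5.41% of calls were unchanged genes. For GPD-SIR3-A2Q against WT the shares were 16%, 78%, 98% and 100% (5453 genes, 7.01%), and for sir3Δ against WT 14%, 78%, 96% and 96% (5452 genes, 2.74%). For GPD-SIR3 against GPD-SIR3-A2Q they were 28%, 78%, 98% and 100% (5456 genes, 7.88%). More genes were planted than limma called in the data, so recovery may be overstated. Libraries were drawn independently, whereas same-numbered libraries of some strains shared deviations.

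Alternatives were no filter, a mean of at least 50, pseudocounts of 0.5 and 10, median-of-ratios rescaling, the replicate number as a block, only the 2 groups compared, and a log2 change of at least 1. Others were limits of 20 and 40 kb, leaving out duplicated families, an estimated camera correlation, 1 fit for genes and non-coding transcripts, each library left out in turn, and DESeq2 1.42.0 and limma-voom on the recovered reads. edgeR 4.0.16 (quasi-likelihood) on the recovered reads was added after the data were seen and called 76, 43, 48 and 76 genes in the 4 comparisons. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. tRNA, snoRNA and snRNA features entered only the non-coding fit, since a scaling to genes does not address their yield.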

Results

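Total RNA of exponentially growing budding yeast, *Saccharomyces cerevisiae* strain W303, was sequenced in 8 libraries, 2 from each of 4 strains. The strains were wild type (WT), a strain expressing SIR3 from the strong constitutive GPD promoter (GPD-SIR3), a strain expressing the A2Q form of SIR3 in the same way (GPD-SIR3-A2Q), and a strain without SIR3 (sir3Δ). Sir3 is the nucleosome-binding subunit of the complex that silences genes near telomeres and at the silent mating-type cassettes, and the A2Q change replaces the alanine after the start methionine with glutamine. The series asks how heterochromatin domains and subtelomeres depend on the dose of Sir3. Reads on genes numbered 16.2 M and 11.9 M in WT 1 and WT 2, 15.6 M and 7.01 M in GPD-SIR3 1 and 2, 12 M and 10.4 M in GPD-SIR3-A2Q 1 and 2, and 18.1 M and 14.5 M in sir3Δ 1 and 2. Levels are scaled read counts, given as mean ± SD (n = 2). Changes are log2 fold changes of the scaled count plus 1, given ± SE of a limma model over all 8 libraries, with p adjusted by the Benjamini-Hochberg method over 5473 genes. The fold changes of low genes are understated on that scale. The labels do not say that the libraries of a strain came from separate cultures, so p-values measure only the spread between these samples. An exact permutation test of 2 libraries against 2 cannot give a p lower than 0.333. Intervals and floors given for low read numbers cover counting error only.

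SIR3 (YLR442C, chromosome XII, 1019315 to 1022251 in build R64) followed the strain labels in every library. Its level was 466 ± 25.5 in WT, 12298 ± 2217 in GPD-SIR3, 13174 ± 60.2 in GPD-SIR3-A2Q and 38.0 ± 1.65 in sir3Δ. It rose by 4.71 ± 0.13 (26.1-fold, limma adjusted p = 4.36e-07) in GPD-SIR3 and by 4.82 ± 0.13 (28.2-fold, limma adjusted p = 3.55e-07) in GPD-SIR3-A2Q. In sir3Δ it fell by 3.58 ± 0.13 (limma adjusted p = 9.71e-07), from 1859 reads over the WT libraries to 177. The 2 overexpressing strains were not distinguished at SIR3 (−0.11 ± 0.13, limma adjusted p = 0.786), and the sign turned without GPD-SIR3 1 (0.07). The genes of the other silencing subunits did not pass limma in any comparison. SIR1, which acts at the silent cassettes, had values of 0.33 ± 0.26, 0.19 and 0.10 in GPD-SIR3, GPD-SIR3-A2Q and sir3Δ against WT. SIR2, the histone deacetylase, had values of −0.80 ± 0.20 (limma adjusted p = 0.167), −0.22 (0.853) and −0.47 (0.574), and DESeq2 called it lower in GPD-SIR3 than in WT (−0.82, adjusted p = 0.0232). SIR4, the scaffold subunit, had values of 0.17 ± 0.13, 0.10 and −0.05.

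At the silent cassettes, HMRA1 (YCR097W, chromosome III, 293835 to 294321), which encodes the a1 regulator, had 0 reads in all 4 libraries of WT and GPD-SIR3. It was at 53.7 ± 6.79 in sir3Δ, from 252 reads, at least 35.1-fold above the floor of 3 counts in each WT library (limma adjusted p = 0.00306). That call ended without sir3Δ 1 (0.0946) or sir3Δ 2 (0.109). In GPD-SIR3-A2Q, HMRA1 was at 10.5 ± 4.12, from 33 reads, at least 6.86-fold above the WT floor. That difference did not pass over all genes (limma adjusted p = 0.0744), and it did when adjusted over the list alone, in which HMRA1 was the 1 tested member. It was called by edgeR (adjusted p = 0.0455), DESeq2 (0.00135) and limma-voom (0.00476), and by limma without a filter on low values (0.00511). HMRA1 was at least 4.83-fold lower in GPD-SIR3 than in GPD-SIR3-A2Q (limma adjusted p = 0.0461), a call that ended without any 1 of the 8 libraries (0.0589 to 0.371), with a pseudocount of 10 (0.173) and with only the 2 groups in the fit (0.285). HMLALPHA1, HMLALPHA2, HMRA2, MATALPHA1 and MATALPHA2 were listed at 0 in every library. These genes have identical copies elsewhere in the genome, and how reads with several matches were counted is not stated, so no level can be read from those zeros.

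In GPD-SIR3 against WT, which asks what a raised dose of Sir3 does along the chromosomes, genes near chromosome ends fell. RDS1, a zinc-cluster regulator 3.16 kb from the right end of chromosome III, fell by 5.85 ± 0.28, from 216 ± 29.3 to 2.90 ± 1.56 (limma adjusted p = 1.12e-05). Its neighbour AAD3, a putative aryl-alcohol dehydrogenase, fell by 5.85 ± 0.44, from 96.0 ± 11 to 0.90 ± 1.27. PHO12, an acid phosphatase, fell by 4.34 ± 0.28, from 800 ± 193 to 39.9 ± 16.8. SEO1, a putative permease (−4.24 ± 0.37), and YIR042C (−3.92 ± 0.34) fell too. Among genes that were abundant in WT, PHO89, a sodium-phosphate cotransporter, fell by 2.70 ± 0.17, from 2096 ± 61.6 to 324 ± 66.6. IRC7, a cysteine lyase, fell from 1770 to 133, ZRT1, the high-affinity zinc transporter, from 2238 to 263, and DLD3, a lactate dehydrogenase, from 2960 to 733. ADH4, an alcohol dehydrogenase (chromosome VII, 15159 to 16307), fell from 301 to 39.7 and IMD2, an IMP dehydrogenase, from 415 to 56.7. These 5 genes were picked after their values were seen. Among the genes above, only AAD3 (25.8%), PHO12 (87.2%) and IMD2 (33.7%) have over 10% of their 50-base stretches elsewhere in the genome, where reads may be shared. YER187W had 2 reads in the GPD-SIR3 libraries against 90 in WT, 2.77% of the WT level (95% exact interval 0.33 to 10.3). YPL279C, with 79.4% of such stretches elsewhere, had 3 against 86, 4.34% (0.879 to 13.1). Of these genes, YER187W lost its call without WT 2 (limma adjusted p = 0.0566) and YPL279C without WT 1 or WT 2 (at most 0.0931), and both lost it with only the 2 groups in the fit (0.0699 and 0.111).

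By distance, 20 of 35 tested genes within 10 kb of an end fell (57.1%), with a median log2 fold change of −2.47, 5.53-fold lower. Of the 78 genes between 10 and 20 kb, 19 fell (24.4%, median −0.27). Of the 120 genes between 20 and 30 kb, FZF1 and ZRT1 fell, and YIL169C and HPF1 rose. Of the 290 genes between 30 and 50 kb, limma called 0, with 24 at an unadjusted p under 0.05, and edgeR called 0, DESeq2 5 and limma-voom 1. Within 30 kb, 41 of 233 genes fell (17.6%), against 18 of 4927 genes beyond 50 kb (0.365%). The odds ratio was 58.1 (95% interval 31.9 to 109, Fisher's exact test, adjusted p = 2.56e-42). Genes that rose numbered 2 within 30 kb and 11 beyond 50 kb (Fisher's exact test, adjusted p = 0.183). The lower shift passed the camera set test within 10 kb (adjusted p = 5.65e-57; adjusted p = 0.0032 with an estimated correlation) and from 10 to 20 kb (adjusted p = 1.11e-21; adjusted p = 0.00399 with an estimated correlation). With only the 2 groups in the fit, 27 genes within 30 kb were called in either direction, in place of 43.

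**Figure D1:**
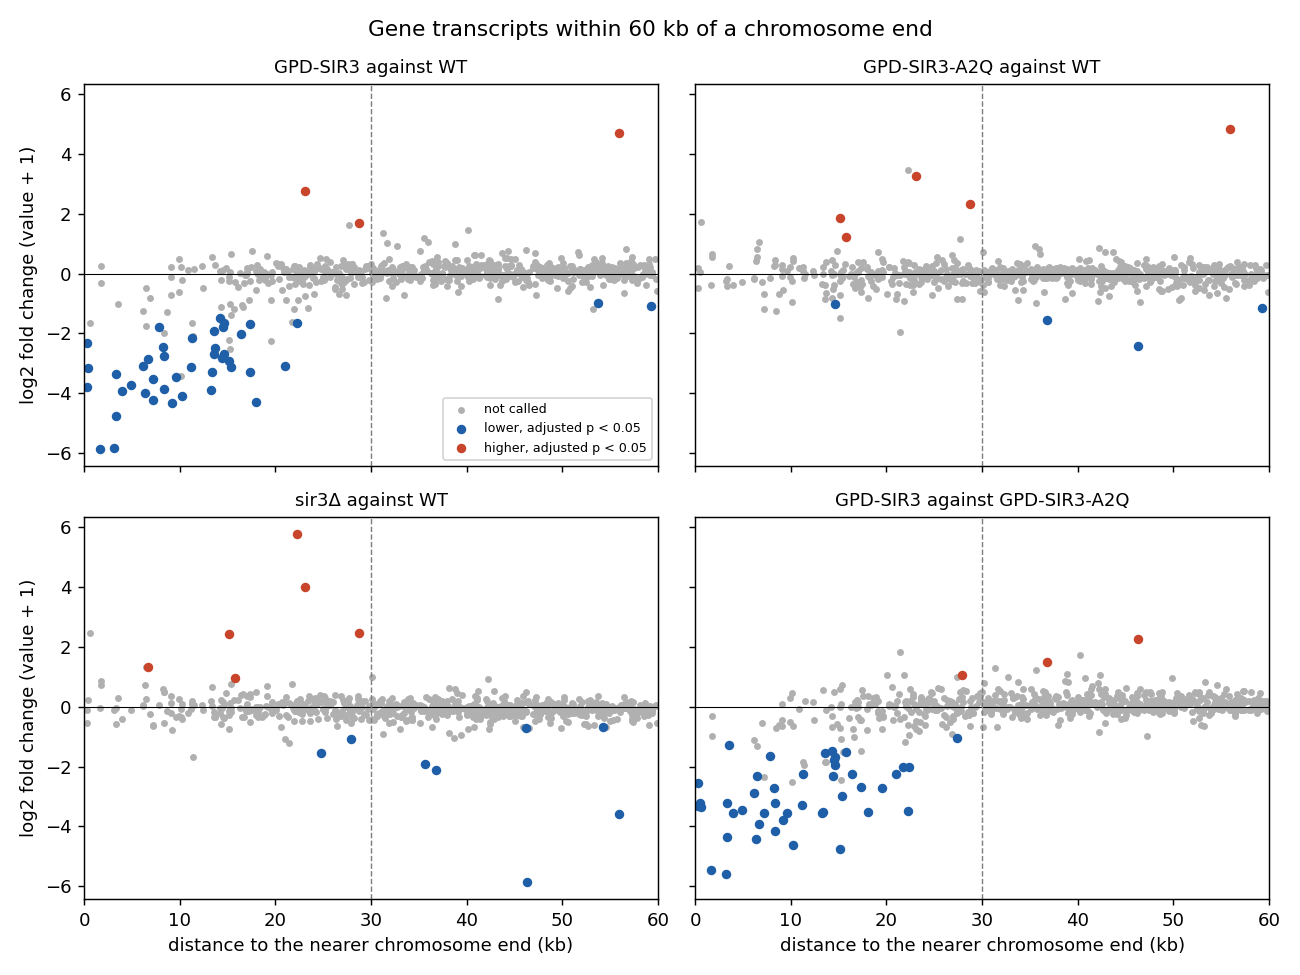
Log2 fold change (scaled read count plus 1) against the distance in kb to the nearer chromosome end, from 0 to 60 kb, 1 panel per comparison; each point is a gene, blue where called lower, red where called higher and grey where not called, and the dashed line marks 30 kb. In GPD-SIR3, 20 of the 35 genes within 10 kb were called lower against WT and 22 of 35 against GPD-SIR3-A2Q, while the panels of GPD-SIR3-A2Q and sir3Δ against WT have no blue point there.

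Lower genes lay at 22 of the 32 chromosome ends that had a tested gene, and the other 10 ends had none. The farthest lower gene of an end was at a median of 12.2 kb and at most at 22.3 kb, where FZF1, a regulator of sulfite export at the left end of chromosome VII, fell by 1.66 (limma adjusted p = 0.011). At the right end of chromosome III, a run of neighbouring genes fell: GIT1, a glycerophosphoinositol permease 18 kb from the end (−4.30 ± 0.32), YCR099C (−3.14), YCR100C (−2.82), YCR101C (−2.69) and YCR102C (−3.12). ADH7, an alcohol dehydrogenase between YCR102C and RDS1, had a value of −1.76 and was not called (limma adjusted p = 0.0767). OCA4 (−0.71, limma adjusted p = 0.206), CDC50 (−0.03) and CDC39 (−0.06), farther from the end than HMRA1, were not called. In GPD-SIR3-A2Q against WT the values of RDS1, AAD3 and GIT1 were −0.25, −0.39 and −0.80, and in sir3Δ they were −0.11, −0.05 and −0.26, none of them called.

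**Figure D2:**
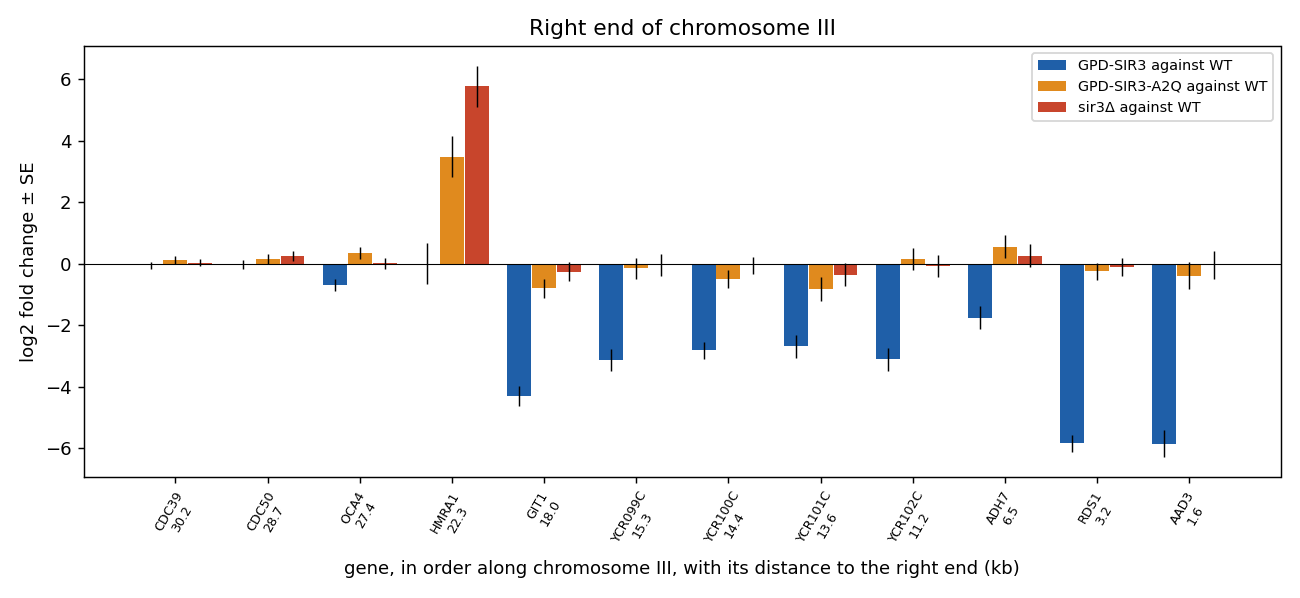
Log2 fold changes (scaled read count plus 1) of genes at the right end of chromosome III against WT, in their order along the chromosome from CDC39 to AAD3 with the distance to the end in kb; bars are estimates and error bars are SEs, for GPD-SIR3, GPD-SIR3-A2Q and sir3Δ. The GPD-SIR3 bars reach −4.30 at GIT1 and −5.85 at RDS1 and AAD3, and the HMRA1 bars stand above 0 in the other 2 strains.

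The COS family and the phosphate regulon, lists with members near chromosome ends, passed camera with either correlation in GPD-SIR3 against WT. Of 8 tested members of the COS family, endosomal membrane proteins, 5 fell (5 when adjusted over the list alone): COS10 (−4.76 ± 0.28), COS8 (from 346 to 20.9), COS1 (−3.87 ± 0.31) and COS6 (−2.47 ± 0.14), with COS9 (−1.80) as the fifth. The set passed camera (adjusted p = 7.67e-15, and adjusted p = 0.0297 with an estimated correlation). Reads may be shared with other genes for COS1, COS6 and COS8, with 71.1%, 38.3% and 17.4% of their 50-base stretches elsewhere in the genome. For COS9 and COS10 the share was 0.851% and 0%. Of 12 phosphate regulon genes, 3 fell (5 adjusted over the list alone), PHO12, PHO11 (−3.37 ± 0.27) and PHO89 (camera adjusted p = 1.24e-13; adjusted p = 0.0484 with an estimated correlation). PHO11 and PHO12 are near-identical copies of one another. Of 18 iron regulon genes, ARN2, a siderophore transporter, fell by 2.75 ± 0.19 (3 rose and 2 fell when adjusted over the list alone). Of 6 AAD genes, AAD3 fell (1 adjusted over the list alone). The hexose transporters (11 tested) and the maltose and sucrose genes (8 tested) had no call over all genes, and 1 and 2 members were lower when adjusted over the list alone.

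Away from the ends, genes of amino acid biosynthesis fell in GPD-SIR3 against WT. Of 32 tested members, 8 fell and none rose (17 fell when adjusted over the list alone), among them ARG1, argininosuccinate synthetase (−1.25 ± 0.20), from 1245 to 518 (limma adjusted p = 0.0184). HIS4, of histidine synthesis (−1.19 ± 0.18), and MET6, methionine synthase (−0.80 ± 0.12), were among them too. Camera passed with its preset correlation (adjusted p = 3.35e-23), and the call was lost otherwise (adjusted p = 0.053 with an estimated correlation). The list count was 1 without WT 1, 0 without WT 2, 2 without GPD-SIR3 1, 1 without GPD-SIR3 2 and 2 without GPD-SIR3-A2Q 1 or GPD-SIR3-A2Q 2. RPS1A (YLR441C, chromosome XII, 1018141 to 1018908), a ribosomal protein gene beside SIR3, fell by 1.09 ± 0.09, from 11087 ± 506 to 5221 ± 72.3 (limma adjusted p = 2.46e-04). It was the 1 member called of 138 ribosomal protein genes (3 adjusted over the list alone; camera adjusted p = 0.461 with an estimated correlation) and of the 3 tested neighbours of SIR3 (2 adjusted over the list alone). MET17, of sulfide assimilation, fell by 0.65 ± 0.13 and was the 1 call of 8 auxotrophic marker genes (1 adjusted over the list alone; camera adjusted p = 0.144 with an estimated correlation). Adenine biosynthesis had 0 limma calls over all genes among 15 members, with 8 at an unadjusted p under 0.05 and 8 lower when adjusted over the list alone. edgeR called 1, DESeq2 6 and limma-voom 1 of them (camera adjusted p = 3.96e-11; adjusted p = 0.297 with an estimated correlation).

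Higher genes in GPD-SIR3 were fewer. YIL169C (chromosome IX, 23119 to 26106), a relative of the cell-wall mannoprotein gene HPF1, rose by 2.77 ± 0.20 (6.83-fold), from 210 ± 35.7 to 1429 ± 76.8 (limma adjusted p = 1.11e-04). HPF1 itself (chromosome XV, 28703 to 31606) rose by 1.69 ± 0.22, and the call ended with only the 2 groups in the fit (limma adjusted p = 0.0549). Reads may be shared, since 17.3% of the 50-base stretches of YIL169C and 13.8% of those of HPF1 occur more than once in the genome. YOL086W-A, a centromere-associated histone-fold protein gene, rose by 2.54 ± 0.22, INO1, inositol-phosphate synthase, by 2.14 ± 0.21 and HSP12, a membrane protein of the stress response, by 2.00 ± 0.27. HSP12 was the 1 call of 21 general stress genes (1 rose and 1 fell when adjusted over the list alone). ULI1 rose by 1.78 ± 0.33, NCE103, carbonic anhydrase, by 1.18, SED1, a cell-wall protein, by 0.94 and SGA1, a glucoamylase, by 0.92. In all, limma called 13 genes higher and 59 lower, 8 and 48 of them by at least 2-fold. The libraries of the 2 groups did not overlap at 1851 of 5473 genes (33.8%, against 33.3% by chance). The count of higher genes was 7 without WT 1, 5 without WT 2, and 6 without GPD-SIR3 2, GPD-SIR3-A2Q 1 or GPD-SIR3-A2Q 2. The count of lower genes was 33 without WT 1 or WT 2. The largest limma adjusted p values with 1 library left out were 0.0607 for HSP12 (WT 2), and 0.273 for ULI1 and 0.282 for SGA1 (each of the 8 libraries). They were 0.236 for NCE103, 0.235 for SED1 and 0.290 for MET17 (each library of WT, GPD-SIR3 and GPD-SIR3-A2Q). They were 0.157 for ARG1 (both libraries of GPD-SIR3 and of GPD-SIR3-A2Q, and WT 2), 0.106 for HIS4 (WT 1, WT 2, GPD-SIR3 1) and 0.115 for MET6 (all 4 libraries of WT and GPD-SIR3). With only the 2 groups in the fit, calls were also lost by ULI1 (limma adjusted p = 0.138), NCE103 (0.0568), SED1 (0.0612), SGA1 (0.242) and MET17 (0.195). SGA1 lost its call in edgeR (adjusted p = 0.0639) and limma-voom (0.0747), and in limma with rescaling (0.0511), no filter (0.0560) or a mean of at least 50 (0.0589), as MET17 did with a mean of at least 50 (0.0623).

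In GPD-SIR3-A2Q against WT, where the substitution and the SIR3 transcript level differ together, genes of mating fell. MF(ALPHA)2, an alpha-factor gene (chromosome VII, 344791 to 345153), fell by 4.09 ± 0.17, 17.1-fold, from 2176 ± 2.35 to 127 ± 9.43 (limma adjusted p = 7.29e-06). All 5 alpha-specific genes fell (5 adjusted over the list alone): MF(ALPHA)2, STE3, the a-factor receptor (−3.06 ± 0.16), YLR040C (from 612 to 76.3), SAG1, the alpha-agglutinin (−2.98 ± 0.18) and MF(ALPHA)1 (−2.57 ± 0.34). Of 12 haploid-specific genes, 11 fell (12 adjusted over the list alone). They included FAR1, which arrests the cell cycle (−2.98 ± 0.23), and the G-protein subunit genes GPA1 (−2.73 ± 0.19) and STE18 (−2.52 ± 0.38). HO, the mating-type endonuclease (−2.43 ± 0.37), and FUS3, a MAP kinase (−2.37 ± 0.32), fell as well. STE4, the beta subunit, fell by 0.93 ± 0.14 (limma adjusted p = 0.0146). NEJ1, an end-joining regulator, was the haploid-specific gene not called (−2.16 ± 0.40, limma adjusted p = 0.0592). Camera gave adjusted p = 9.37e-22 for the alpha-specific list (adjusted p = 0.0439 with an estimated correlation) and 6.05e-33 for the haploid-specific list (adjusted p = 0.00551 with an estimated correlation). Of 13 pheromone response genes, SST2, a regulator of G-protein signalling, fell by 1.54 ± 0.18 (5 fell when adjusted over the list alone; camera adjusted p = 0.132 with an estimated correlation). The haploid-specific count was 7 without WT 1, 6 without WT 2, 3 without GPD-SIR3-A2Q 1 and 5 without GPD-SIR3-A2Q 2. The limma adjusted p reached 0.131 for MF(ALPHA)1, 0.311 for STE18, 0.184 for HO and 0.122 for FUS3, each lost without any 1 of the 4 libraries of WT and GPD-SIR3-A2Q, and 0.0583 for SST2 without GPD-SIR3-A2Q 2.

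IME4 (chromosome VII, 142246 to 144048), an mRNA methyltransferase of meiotic entry, rose by 4.98 ± 0.48 in GPD-SIR3-A2Q, from 1.37 ± 1.11 (6 reads) to 70.1 ± 11.8 (limma adjusted p = 0.0011). YIL169C rose by 3.25 ± 0.20 to 2006 ± 410, YOL086W-A by 2.46 to 519, HPF1 by 2.34 to 1588 and ADH4 by 1.84 ± 0.17, from 301 ± 16.3 to 1082 ± 14.2. CHA1, a serine and threonine deaminase 15.8 kb from an end, rose by 1.22, from 422 to 992. Lower genes outside mating included ARG4, argininosuccinate lyase (−1.46 ± 0.20), HIS4 (−1.02) and MET6 (−0.97), the 3 amino acid biosynthesis genes called of 32 (1 rose and 13 fell when adjusted over the list alone; camera adjusted p = 0.189 with an estimated correlation). RPS1A fell by 1.16 ± 0.09 to 4965, and with RPS9A (−1.12) made 2 of 138 ribosomal protein genes (2 adjusted over the list alone; camera adjusted p = 0.838 with an estimated correlation). RPS1A was also the 1 call among the SIR3 neighbours (3 adjusted over the list alone). PHO89 fell by 1.03 to 1024, the 1 call of 12 phosphate genes (1 adjusted over the list alone; camera adjusted p = 0.281 with an estimated correlation).

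Few genes near chromosome ends were called in GPD-SIR3-A2Q against WT. Within 10 kb limma called 0 of 35 genes, with 5 at an unadjusted p under 0.05 and 1 call each by edgeR, DESeq2 and limma-voom (camera adjusted p = 0.422). Within 30 kb, 1 gene fell (PHO89) against 31 beyond 50 kb (Fisher's exact test, adjusted p = 1). The 4 genes that rose within 30 kb, CHA1, ADH4, YIL169C and HPF1, compared with 3 beyond 50 kb (odds ratio 28.6, 95% interval 4.81 to 196, Fisher's exact test, adjusted p = 0.000255). That test counts genes as independent, and YIL169C and HPF1 are relatives. Camera passed neither from 10 to 20 kb (adjusted p = 0.636) nor from 20 to 30 kb (adjusted p = 0.436). In all, 7 genes rose and 34 fell, 7 and 28 of them by at least 2-fold, and the libraries did not overlap at 39.8% of genes, against 33.3% by chance. Without 1 library, the lower count was 19 (WT 1), 14 (WT 2), 10 (GPD-SIR3-A2Q 1) or 15 (GPD-SIR3-A2Q 2), and within 30 kb 3 genes were called without any 1 of these 4. Without any 1 of them CHA1 (limma adjusted p up to 0.161), HIS4 (0.650) and PHO89 (0.321) also lost their calls, and HIS4 lost its call with no filter (0.0522) or a mean of at least 50 (0.0549). ARG4 (0.158) and RPS9A (0.116) lost theirs without GPD-SIR3-A2Q 1, GPD-SIR3-A2Q 2 or WT 2, and MET6 (0.0772) without GPD-SIR3-A2Q 1 or WT 2. The amino acid count was 0 without GPD-SIR3-A2Q 1 or WT 2, 1 without GPD-SIR3-A2Q 2 and 2 without WT 1.

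In sir3Δ against WT, which asks what loss of Sir3 does, genes of mating fell. MF(ALPHA)1 (chromosome XVI, 193648 to 194145) fell by 9.15 ± 0.34, 569-fold, from 3047 ± 152 to 4.89 ± 3.49 (limma adjusted p = 9.71e-07). MF(ALPHA)2 fell by 8.18 ± 0.17, 291-fold, from 2176 to 6.49. STE3 (chromosome XI, 113215 to 114627) fell by 5.88 ± 0.16, from 2160 to 35.9. All 5 alpha-specific genes fell (5 adjusted over the list alone), the others being YLR040C (−5.36 ± 0.28) and SAG1 (−3.63). All 12 haploid-specific genes fell (12 adjusted over the list alone). FUS3 fell by 6.43 ± 0.32, from 457 to 4.55. HO (−5.85 ± 0.37) and AXL1, a protease of a-factor processing and bud-site choice (−4.52 ± 0.18), followed. STE18 had 1 read in the sir3Δ libraries against 355 in WT, 0.243% of the WT level (95% exact interval 0.00615 to 1.37). The other haploid-specific genes were FAR1 (−4.28), GPA1 (−4.24), STE4 (−3.87), RME1 (−3.69), STE5 (−3.24), NEJ1 (−3.01), RDH54 (−2.30) and AMN1 (−1.29). Of 13 pheromone response genes, 3 fell (6 adjusted over the list alone): FUS1, of cell fusion (−2.70 ± 0.40), SST2 (−2.13) and KAR4, a mating transcription factor (−1.08). Camera gave adjusted p = 5.39e-29 for the alpha-specific list (adjusted p = 0.0253 with an estimated correlation) and 2.64e-50 for the haploid-specific list (adjusted p = 0.00234 with an estimated correlation). The pheromone response list also passed with an estimated correlation (adjusted p = 0.0491 with an estimated correlation). Its count was 1 without WT 1, WT 2, sir3Δ 1 or sir3Δ 2, where FUS1 lost its call (limma adjusted p up to 0.150), and KAR4 lost its call without any 1 library of WT, GPD-SIR3-A2Q or sir3Δ (up to 0.424). KAR4 was also not called by edgeR (adjusted p = 0.0837) or limma-voom (0.0765). It was not called by limma with rescaling (0.0903), no filter (0.0624), a mean of at least 50 (0.0562), a pseudocount of 10 (0.0506) or only the 2 groups in the fit (0.126).

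IME4 rose by 5.80 ± 0.48 in sir3Δ, to 124 ± 10.9 (limma adjusted p = 2.04e-04). YIL169C rose by 4.01 ± 0.20 (16.1-fold) to 3420 ± 810, HPF1 by 2.48 ± 0.22 to 1756, ADH4 by 2.43 ± 0.17 to 1631 ± 103 and IMD2 (chromosome VIII, 554396 to 555967) by 1.32 ± 0.22 to 1023. Of 32 amino acid biosynthesis genes, 3 rose (7 adjusted over the list alone), ARG1 by 1.09, LYS20, homocitrate synthase, by 1.01 and LYS9, of lysine synthesis, by 0.64 (camera adjusted p = 4.26e-20; adjusted p = 0.0491 with an estimated correlation). CHA1 rose by 0.95. The COS family passed camera upward (adjusted p = 2.38e-06; adjusted p = 0.0491 with an estimated correlation) with 0 members called by limma over all genes, 4 at an unadjusted p under 0.05 and 2 adjusted over the list alone. edgeR called 1, and DESeq2 and limma-voom called 2. ECM7, a calcium-uptake protein gene beside SIR3, fell by 0.68, the 1 call of the 3 SIR3 neighbours (1 adjusted over the list alone). Within 30 kb, 6 genes rose, ADH4, IMD2, CHA1, YIL169C, HPF1 and HMRA1, and 2 fell, VBA2 (−1.53) and KAR4. Beyond 50 kb, 4 rose and 37 fell (higher: odds ratio 32.4, 95% interval 7.63 to 157, Fisher's exact test, adjusted p = 3.83e-06; lower: adjusted p = 0.927). Here too the test counts the relatives YIL169C and HPF1 as independent. The upward shift within 10 kb (camera adjusted p = 0.00124; adjusted p = 0.241 with an estimated correlation) and from 10 to 20 kb (camera adjusted p = 0.042; adjusted p = 0.281 with an estimated correlation) did not hold with an estimated correlation.

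In all, 10 genes rose and 43 fell in sir3Δ, 8 and 33 of them by at least 2-fold, and the libraries did not overlap at 39.5% of genes, against 33.3% by chance. Without 1 library, the higher count was 6 (GPD-SIR3-A2Q 1 or GPD-SIR3-A2Q 2), 5 (WT 2) or 4 (sir3Δ 2), and the lower count was 21 (WT 1), 23 (WT 2), 26 (sir3Δ 1) or 21 (sir3Δ 2). The count within 30 kb was 5 without WT 1, GPD-SIR3-A2Q 1 or GPD-SIR3-A2Q 2, 4 without WT 2 or sir3Δ 1 and 3 without sir3Δ 2. The amino acid count was 0 without WT 2 or sir3Δ 2 and 1 without WT 1, GPD-SIR3-A2Q 1 or GPD-SIR3-A2Q 2. IMD2 (limma adjusted p up to 0.183) lost its call without GPD-SIR3-A2Q 1, GPD-SIR3-A2Q 2, WT 2 or either sir3Δ library. ARG1 (0.377) lost its call without any 1 library other than sir3Δ 1, and LYS20 (0.0831) without WT 2 or either sir3Δ library. CHA1 (0.336) lost its call without any 1 library of WT or GPD-SIR3-A2Q or without sir3Δ 2. LYS9 (0.183) and ECM7 (0.326) lost theirs without any 1 library of WT, GPD-SIR3-A2Q or sir3Δ. With only the 2 groups in the fit, IMD2 (limma adjusted p = 0.0645), ARG1 (0.234), CHA1 (0.115), LYS9 (0.0815) and ECM7 (0.143) were not called. ARG1 was also lost in limma with no filter (0.0540), a mean of at least 50 (0.0602) or a pseudocount of 10 (0.0504). ECM7 was lost in edgeR (adjusted p = 0.0905), limma-voom (0.0765) and limma with rescaling (0.113).

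**Figure D3:**
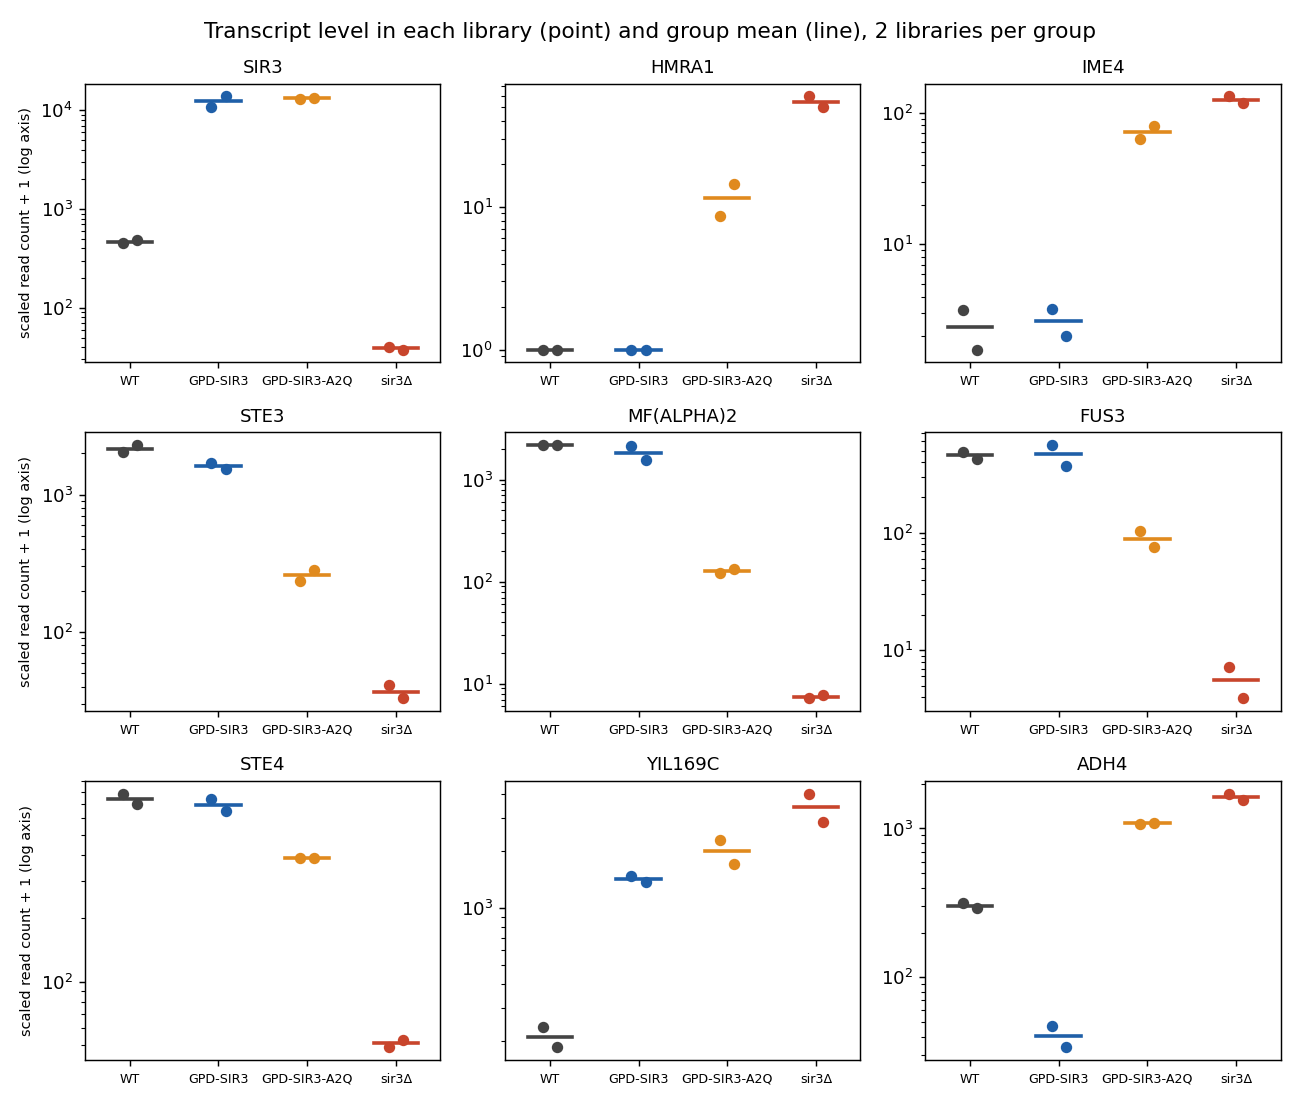
Scaled read count plus 1 (log axis) of SIR3, HMRA1, IME4, STE3, MF(ALPHA)2, FUS3, STE4, YIL169C and ADH4 in the 4 strains; points are libraries and lines are group means. MF(ALPHA)2 stands at 2176 in WT, 127 in GPD-SIR3-A2Q and 6.49 in sir3Δ, and ADH4 at 301 in WT, 39.7 in GPD-SIR3 and 1631 in sir3Δ.

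GPD-SIR3 was compared with GPD-SIR3-A2Q directly, which sets the unaltered protein against the substituted one at SIR3 levels of 12298 and 13174. Near the ends, RDS1 was lower in GPD-SIR3 by a log2 value of −5.60 ± 0.28, AAD3 by −5.46 ± 0.44 and ADH4 by −4.75 ± 0.17, at 39.7 ± 9.43 against 1082 ± 14.2 (limma adjusted p = 2.70e-06). IMD2 (−3.92, at 56.7 against 860), PHO12 (−3.80) and PHO89 (−1.67) were lower as well. YER187W had 2 reads against 109, 1.83% of the GPD-SIR3-A2Q level (95% exact interval 0.218 to 6.75). Within 10 kb, 22 of 35 genes were lower (62.9%, median −2.72), from 10 to 20 kb 18 of 78 (23.1%, median −0.41), and from 20 to 30 kb OCA4, HMRA1, FZF1, ZRT1 and BSC5 were lower and KAR4 higher of 120. Within 30 kb this made 45 of 233 lower (19.3%), against 3 beyond 50 kb, IME4 (−4.79 ± 0.48), TNA1, a nicotinic acid permease (−1.09), and LEU9, of leucine synthesis (−0.56). The odds ratio was 387 (95% interval 124 to 2078, Fisher's exact test, adjusted p = 4.6e-58). Camera passed within 10 kb (adjusted p = 5.32e-60; adjusted p = 0.0032 with an estimated correlation) and from 10 to 20 kb (adjusted p = 2.23e-23; adjusted p = 0.00399 with an estimated correlation). From 20 to 30 kb it did not with an estimated correlation (adjusted p = 0.0211; adjusted p = 0.335 with an estimated correlation). Lower genes lay at 23 of 32 ends, the farthest at a median of 13.4 kb and at most at 27.4 kb (OCA4, −1.05, limma adjusted p = 0.0316). ADH7, not called against WT, was lower here (−2.31, limma adjusted p = 0.0171). The count within 30 kb was 26 without GPD-SIR3-A2Q 2, and the count of lower genes, 48, was then 27. LEU9 lost its call without any 1 library other than GPD-SIR3 1 (limma adjusted p up to 0.338).

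The mating genes were higher in GPD-SIR3 than in GPD-SIR3-A2Q. All 5 alpha-specific genes were higher (5 adjusted over the list alone; camera adjusted p = 0.0483 with an estimated correlation), among them MF(ALPHA)2 by 3.83 ± 0.17, at 1835 ± 417 against 127, SAG1 by 3.39 ± 0.18, MF(ALPHA)1 by 2.91 and STE3 by 2.65. All 12 haploid-specific genes were higher (12 adjusted over the list alone; camera adjusted p = 0.00855 with an estimated correlation), among them FAR1 by 3.03, GPA1 by 2.70, STE18 by 2.57, FUS3 by 2.37 and HO by 2.27. Of 13 pheromone response genes, 4 were higher (6 adjusted over the list alone; camera adjusted p = 0.0616 with an estimated correlation), AGA1, an agglutinin anchor, by 1.59, SST2 by 1.49, KAR4 by 1.06 and PRM5 by 0.79. Against WT, GPD-SIR3 had 0 limma calls in these 3 lists, over all genes or adjusted over the list alone, and edgeR, DESeq2 and limma-voom also called 0. At an unadjusted p under 0.05 there were then 1 alpha-specific, 0 haploid-specific and 2 pheromone response genes. Of 8 COS genes, 5 were lower in GPD-SIR3 than in GPD-SIR3-A2Q (6 adjusted over the list alone; camera adjusted p = 0.00855 with an estimated correlation), among them COS8 (−4.42), COS10 (−4.35), COS1 (−4.15) and COS6 (−2.72). Of 12 phosphate genes, 3 were lower (4 adjusted over the list alone; camera adjusted p = 0.0617 with an estimated correlation), PHO12, PHO11 (−3.20) and PHO89. AAD3 (1 of 6 adjusted over the list alone; camera adjusted p = 0.15 with an estimated correlation), ARN2 (−3.22) and HXT9 (−2.72, 4 reads against 47) were the calls of the AAD, iron and hexose lists, and LEU9 that of amino acid biosynthesis (1 adjusted over the list alone; camera adjusted p = 0.322 with an estimated correlation). Adjusted over the list alone, 2 iron genes and 2 hexose transporters were higher, and 2 and 3 lower.

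In all, 32 genes were higher and 48 lower in GPD-SIR3 than in GPD-SIR3-A2Q, 21 and 47 of them by at least 2-fold, and the libraries did not overlap at 41.0% of genes, against 33.3% by chance. The count of higher genes was 15 without GPD-SIR3-A2Q 1 and 16 without GPD-SIR3-A2Q 2, and the haploid-specific count was 8 and 7. The pheromone response count was 1 without either GPD-SIR3-A2Q library and 2 without GPD-SIR3 1 or any 1 library of WT or sir3Δ. The limma adjusted p reached 0.104 for STE18 (GPD-SIR3-A2Q 1, GPD-SIR3-A2Q 2, GPD-SIR3 2), 0.0853 for FUS3 (GPD-SIR3-A2Q 2) and 0.173 for HO (GPD-SIR3 1, GPD-SIR3-A2Q 1, GPD-SIR3-A2Q 2). It reached 0.401 for AGA1 (each library other than GPD-SIR3 1), 0.270 for KAR4 (each other than GPD-SIR3 2), 0.198 for PRM5 (both libraries of each of the 2 groups) and 0.342 for HXT9 (each of the 8 libraries). With only the 2 groups in the fit, LEU9 (limma adjusted p = 0.118), HXT9 (0.250), AGA1 (0.101) and KAR4 (0.0971) were not called. AGA1 was also lost in limma-voom (adjusted p = 0.175), and in limma with no filter (0.0565), a mean of at least 50 (0.0655) or a pseudocount of 10 (0.0517), where HXT9 was lost too (0.124). KAR4 was lost in edgeR (adjusted p = 0.0590), limma-voom (0.0700) and limma with rescaling (0.0664).

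Of the fixed lists, 16 with 219 tested members had 0 limma calls over all genes in the 4 comparisons, with 91 values at an unadjusted p under 0.05, and edgeR called 1, DESeq2 13 and limma-voom 1. They were a-specific genes (such as STE2 and STE6), adenine biosynthesis (ADE5,7 and ADE6), biotin (VHT1 and BIO2), DAN and TIR cell wall genes (TIR3 and DAN4), ergosterol (ERG11 and ERG13) and flocculins (FLO1 and FLO5). The rest were glycolysis (PDC1 and ENO2), heat shock (SSA2 and SSE1), histones (HHT2 and HTA1), maltose and sucrose use (SUC2 and MAL13), meiosis and sporulation (IME2 and SPO1), the PAU family (PAU17 and PAU7), ribosome biogenesis (NOG2 and RRP5), silencing and telomere proteins (RAP1 and RPD3), the TCA cycle and respiration (ACO1 and ATP2), and thiamine and vitamin B6 (PHO3 and THI3). The Y′ helicase genes had 0 of 8 members above the filter. Adjusted over the list alone, 2 adenine genes were lower in GPD-SIR3-A2Q than in WT, and 3 TCA cycle and 3 histone genes were higher, and 1 flocculin and 1 maltose gene lower, in GPD-SIR3 than in GPD-SIR3-A2Q. With an estimated correlation, 2 of the 7 lists past camera in GPD-SIR3 against WT held, the COS family and the phosphate regulon, and 2 of 14 in GPD-SIR3-A2Q against WT, the alpha- and haploid-specific genes. In sir3Δ against WT 5 of 9 held, these 2 with pheromone response, amino acid biosynthesis and the COS family, and in GPD-SIR3 against GPD-SIR3-A2Q 3 of 14, alpha- and haploid-specific genes and the COS family.

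Non-coding transcripts were tested in a limma fit of their own, with 3093 past the filter, 279 of them within 30 kb. They included XUTs (sensitive to the nuclease Xrn1), CUTs (cryptic unstable) and SUTs (stable unannotated), many of which overlap and share reads. In GPD-SIR3 against WT, 76 fell and 1 rose, with 69 of the lower ones within 30 kb, where the median was −0.67. By class the lower ones were 27 XUTs, 23 SUTs, 22 of the class chunXUT, 3 CUTs and 1 of the class XUT-A. XUT0189, antisense to ADH7, fell by 5.19 ± 0.44, from 60.3 to 0.90 (limma adjusted p = 5.69e-05). In GPD-SIR3-A2Q against WT limma called 0, with 234 at an unadjusted p under 0.05, and edgeR called 3 and a limma fit together with the genes 7. In sir3Δ against WT, 29 fell and 2 rose, with 6 and 2 within 30 kb. 3F-130, which overlaps HMRA1, rose by 5.52 and SUT108 by 2.21, while XUT1052 (−4.87), XUT0820 (−4.86) and XUT1549 (−4.23) fell. In GPD-SIR3 against GPD-SIR3-A2Q, 78 were lower, 73 of them within 30 kb, and 13 higher. Without 1 library, the sum of calls in GPD-SIR3 against WT, 77, was 32 (WT 1), 39 (WT 2) or 49 (GPD-SIR3 2). In GPD-SIR3-A2Q against WT it was 15 without GPD-SIR3-A2Q 2, and in GPD-SIR3 against GPD-SIR3-A2Q it was 51 and 57 without GPD-SIR3 1 and GPD-SIR3 2 in place of 91. XUT0731, which lies inside YIL169C on the other strand, was at 1046 in WT against 210 for the gene and at 145 in sir3Δ against 3420, so the strands were counted apart.

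The changes against WT were set side by side over 5473 genes, which are not independent replicates. GPD-SIR3-A2Q and sir3Δ shared 5 higher genes, IME4, YIL169C, HPF1, ADH4 and CHA1, and 20 lower genes, which were alpha- or haploid-specific other than TEC1, OPI3, GAP1 and SST2, with independent lists giving 0.0128 and 0.267. SIR3 went opposite ways. GPD-SIR3 and GPD-SIR3-A2Q shared 4 higher genes, SIR3, YIL169C, HPF1 and YOL086W-A, and 10 lower genes, among them GAP1, the general amino acid permease, MET3, MET14 and RPS1A, with independent lists giving 0.0166 and 0.367. ADH4 went opposite ways. GPD-SIR3 and sir3Δ shared 2 higher genes, YIL169C and HPF1, and 1 lower gene, GAP1, with independent lists giving 0.0238 and 0.464. ADH4, IMD2, SIR3 and ARG1 went opposite ways there. Pearson's r was 0.62 for GPD-SIR3-A2Q and sir3Δ (Spearman's rho 0.51), 0.30 (0.36) for GPD-SIR3 and GPD-SIR3-A2Q and 0.02 (0.04) for GPD-SIR3 and sir3Δ. Simulating unchanged groups against the WT libraries 100 times gave 0.50, 0.49 and 0.49, with mean overlaps of 0.07, 0.09 and 0.13 genes. The covariances were 0.0907, 0.0444 and 0.00295, against simulated values of 0.0322, 0.0324 and 0.0324. Splitting WT would leave 1 library a part, so the controls were not split. For GPD-SIR3-A2Q and sir3Δ, r and covariance lay above the simulated values, and part of that excess may come from the shared controls. For GPD-SIR3 and GPD-SIR3-A2Q, the covariance lay above its simulated value and r below. Both lay below for GPD-SIR3 and sir3Δ, less than unchanged groups with shared controls gave. Without 1 library, r for GPD-SIR3 and GPD-SIR3-A2Q was 0.17 (GPD-SIR3 1) or 0.53 (WT 2), and r for GPD-SIR3 and sir3Δ was 0.12 (WT 1) or 0.24 (WT 2).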

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

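The direct comparisons of GPD-SIR3 and of GPD-SIR3-A2Q with sir3Δ, and all tests in this part other than the matched gene sets and the search for genes kept near an end, were chosen after the result was seen. In 6 cases a gene that changed one way against WT in 1 strain changed the other way in another, and the difference itself passed limma with Benjamini-Hochberg adjustment. Given 2 opposite calls against the same WT libraries, that difference is larger than either change. Its p is therefore no separate support for the calls. The calls of IMD2 and ARG1 in sir3Δ against WT depended on single libraries, as given above. ADH4 was lower in GPD-SIR3 than in GPD-SIR3-A2Q (−4.75 ± 0.17, limma adjusted p = 2.70e-06) and than in sir3Δ (−5.34 ± 0.17, limma adjusted p = 2.40e-07). IMD2 was lower in GPD-SIR3 than in sir3Δ (−4.17 ± 0.22, limma adjusted p = 4.53e-06), and so was ARG1 (−2.34 ± 0.20, limma adjusted p = 1.68e-04). SIR3 was higher than in sir3Δ by 8.29 ± 0.13 in GPD-SIR3 (limma adjusted p = 2.91e-09) and by 8.40 ± 0.13 in GPD-SIR3-A2Q (limma adjusted p = 2.59e-09), which follows from the strains' construction.

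In GPD-SIR3, 41 genes within 30 kb of an end fell against WT. Low expression near ends was examined with 1000 sets of genes beyond 50 kb, matched on mean value over all 8 libraries. These sets held at most 4 lower calls (mean 0.487), so genes of like level farther in were seldom called. Only 18 genes beyond 50 kb fell, so no set could have held 41, and the draws add little to the counts by distance. Reads shared in duplicated families are argued against for 24 of the 41, which lie outside those families with at most 10% of their sequence found elsewhere (17 do not). Loss of end DNA from every cell is argued against for 9 of the 24, whose share of the WT value less 2 SE stays over 10%, such as PHO89 (15.5%) and DLD3 (24.8%). It is also argued against for 2 others with such a gene, of a mean of at least 50 in WT, nearer the end, ZRT1 (ADH4) and SRY1 (FRE2). Of the 9, ADH4 clears the limit least, at 10.5% less 2 SE. For the other 13, among them IRC7 (7.49%), such loss could not be told apart from lower transcription by these limits. ADH7 (−1.76 ± 0.38, not called) keeps over 10% less 2 SE and was left out by its mean in WT alone. It lies nearer the end than GIT1, YCR099C, YCR100C and YCR101C, so for these genes the answer depends on that condition. SIR3, deleted in sir3Δ, still showed 8.15% of its WT value there (10.1% plus 2 SE). The limit of 10% rests on that 1 gene. The search set beforehand took genes outside the families with a mean of at least 50 in WT. It asked for more than 2 ends where such a gene kept at least 50% nearer the end than a lower gene. Only 1 end had any (FRE2, 91.1%), so the search could not decide. Repression by the extra Sir3, the difference the strains were built for, may account for the pattern and stays open as a hypothesis, as does loss of some ends in part of the cells.

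In GPD-SIR3-A2Q, the 17 alpha- and haploid-specific genes stood between their WT and sir3Δ levels. A fixed mix of WT-like and sir3Δ-like cells is argued against. The share of sir3Δ-like cells each gene implies runs from 51.2% (STE4) to 95% (SAG1). The weighted variance of these shares is 11.6 times that of error alone (16 degrees of freedom). RNA or cells of the sir3Δ strain in these libraries are argued against, since RPS1A, near its WT level in sir3Δ, allows a share of at most 45.0% ± 2.82 (SE), below the implied share of each of the 17 genes (median 83.4%). HMRA1 stood at 19.5% of its sir3Δ level and IME4 at 55.6% ± 18.9. Partial loss of silencing at HMR in each cell, with genes that respond to different degrees, may account for this and stays open as a hypothesis, as does a mix of more than these kinds of cells.

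YIL169C and HPF1 rose in all 3 strains against WT. Of their 50-base stretches, 17.3% and 13.8% occur more than once in the genome, so reads may be shared. Extra copies or better mapping of the regions are argued against, since the 5 antisense transcripts over the genes did not rise with them. The medians of these transcripts were −0.65, −1.27 and −2.59 in GPD-SIR3, GPD-SIR3-A2Q and sir3Δ, the highest being −0.65. All 5 were called lower in sir3Δ, but 0 in GPD-SIR3 and 0 in GPD-SIR3-A2Q. In the 2 GPD strains the argument therefore rests on the absence of a rise, not on a called fall. Some of the 5 overlap one another, so they are not separate evidence. Low values peculiar to the WT libraries cannot be told apart from a change in each strain for either gene. YIL169C differed between GPD-SIR3 and sir3Δ (−1.24, limma adjusted p = 0.00821), and HPF1 did not pass (−0.79, limma adjusted p = 0.0924). Between GPD-SIR3-A2Q and sir3Δ neither gene passed (YIL169C −0.76, limma adjusted p = 0.27, and HPF1 −0.14, limma adjusted p = 0.937). A difference between 2 other strains does not tell whether the WT values are low. No biological explanation was tested.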

How the results depend on the processing

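edgeR and the left-out libraries for lists, non-coding transcripts and shared changes were chosen after seeing the data; the other alternatives were not. Of the named genes followed through the alternatives, those that turned their sign in any were SIR1, SIR4 and, between the 2 GPD strains, SIR3, none of them called there. Of the calls on genes named by the rule, 18 of 30 in GPD-SIR3 against WT, 12 of 23 in GPD-SIR3-A2Q against WT, 15 of 24 in sir3Δ against WT and 22 of 31 in GPD-SIR3 against GPD-SIR3-A2Q passed with each library left out, and 21, 22, 18 and 26 passed in every other setting. DESeq2 called all 72, 41, 53 and 80 genes that limma called, among 122, 72, 84 and 115, and edgeR 70, 39, 47 and 75 of them. Where a count below moved, the cause was not tested, except where fewer samples or a stricter limit entered by construction. Depth limits HMRA1, YER187W, YPL279C and STE18, each with 3 reads or fewer in a group. Median-of-ratios rescaling moved the median gene by at most 0.077 and the share of higher calls from 18.1% to 13.8%, 17.1% to 17.5%, 18.9% to 22.9% and 40% to 34.6%.

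DESeq2 gave 24 higher and 98 lower genes in GPD-SIR3 against WT, 16 and 56 in GPD-SIR3-A2Q against WT, 27 higher in sir3Δ against WT and 49 higher in GPD-SIR3 against GPD-SIR3-A2Q. With only the 2 groups in the fit, GPD-SIR3 against WT had 5 higher and 35 lower genes and 27 within 30 kb, and sir3Δ against WT 5 within 30 kb. A log2 change of at least 1 left 8 higher genes in GPD-SIR3 against WT and 21 in GPD-SIR3 against GPD-SIR3-A2Q. A limit of 20 kb left 3 genes in GPD-SIR3-A2Q and 3 in sir3Δ against WT. An estimated camera correlation left 2, 2, 5 and 3 lists, and 0 of 2 distance bins in sir3Δ against WT. Of non-coding transcripts in GPD-SIR3-A2Q against WT, where the separate limma fit called 0, with 234 at an unadjusted p under 0.05, 1 fit with the genes called 7 and edgeR 3. SIR4, not called anywhere, turned its sign in sir3Δ against WT (edgeR 0.0165, DESeq2 0.0229, limma-voom 0.0240, rescaling 0.0228; −0.05 as reported) and in GPD-SIR3 against GPD-SIR3-A2Q (edgeR −0.00479, DESeq2 −0.0141, limma-voom −0.00586, rescaling −0.0116; 0.06 as reported).

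Deviations of same-numbered libraries correlated at 0.65 for WT and sir3Δ and at 0.39 for GPD-SIR3 and GPD-SIR3-A2Q, over 4947 genes. For the other pairs of strains the values were −0.02, −0.01, 0.09 and 0.09. Same-numbered libraries thus shared deviations between WT and sir3Δ, and less so between the GPD strains, but not across all strains. The main fit had no term for this. The replicate block gave 30 higher genes in GPD-SIR3 and 11 in GPD-SIR3-A2Q against WT, and 111, 54, 68 and 98 calls in all, sharing 72, 41, 53 and 79 with the fit without it.

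With 1 library left out, the lone library of its group is assumed to vary like the other groups. In GPD-SIR3 against WT, 5 to 15 genes were higher and 33 to 53 lower, 8 to 12 lists passed and 32 to 86 non-coding transcripts were called. In GPD-SIR3-A2Q against WT, 10 to 35 genes were lower, 3 to 6 were called within 30 kb, 9 to 14 lists passed, 0 to 15 non-coding transcripts were called, and SIR1 lay between −0.0608 and 0.442. In sir3Δ against WT, 4 to 13 genes were higher, 21 to 46 lower and 3 to 9 called within 30 kb, and SIR1 lay between −0.15 and 0.35 and SIR4 between −0.129 and 0.0222. In GPD-SIR3 against GPD-SIR3-A2Q, 15 to 35 genes were higher, 27 to 48 lower and 26 to 46 called within 30 kb, 51 to 91 non-coding transcripts were called and SIR3 lay between −0.30 and 0.0737. Pearson's r was 0.17 to 0.53 for GPD-SIR3 and GPD-SIR3-A2Q, −0.0487 to 0.24 for GPD-SIR3 and sir3Δ, and 0.50 to 0.72 for GPD-SIR3-A2Q and sir3Δ.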

Other observations

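The genes of this paragraph were picked by hand after their values were seen, and no list or enrichment test stands behind them. MET3, ATP sulfurylase, fell by 1.14 in GPD-SIR3 and fell by 1.23 in GPD-SIR3-A2Q against WT, as did MET14, APS kinase (−1.20 and −1.12), and MET5, a subunit of sulfite reductase (−0.98 and −1.04). In sir3Δ these 3 had values of 0.38, 0.13 and 0.31 and were not called. MET10, the other subunit, fell by 0.99 in GPD-SIR3 and had a value of −0.71 in GPD-SIR3-A2Q. MEP2, an ammonium permease (−0.73 and −1.25), and ARG7, of arginine synthesis (−0.98 and −0.85), fell in both GPD strains, and GAP1 in all 3 strains, from 2626 in WT to 1308, 866 and 1514.

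Beside IME4, which rose in sir3Δ, the neighbouring open reading frame YGL193C fell by 3.13 (limma adjusted p = 0.0326), and in GPD-SIR3-A2Q it had a value of −2.16 (limma adjusted p = 0.227). RPS1A, beside SIR3, was at −1.09 and −1.16 in the strains with the GPD promoter and at −0.01 in sir3Δ. YOL086W-A was at 2.54, 2.46 and −0.13. The labels give no batch, so a difference between the times at which strains were grown cannot be separated from the strain.

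Of the 2 tests that follow, the one on neighbours was chosen after the result was seen. In sir3Δ, 29 non-coding transcripts fell, and the 23 of them beyond 30 kb from an end were merged into 12 separate regions. Of these regions, 7 lay within 2 kb of a gene that fell, against a mean of 0.367 and at most 3 in 1000 random draws. The 6 within 30 kb lie over or beside YIL169C and HPF1, which rose, and go against the pattern. With them the count was 7 of 15 regions, against at most 4 in the draws. XUT1052 lay 207 bp from NEJ1, XUT0820 427 bp from FAR1, XUT0912 458 bp from STE3, XUT1549 839 bp from MF(ALPHA)1, 16R-348 234 bp from AXL1, 12F-90 278 bp from YLR040C and XUT0197 1770 bp from HO. All 7 lie upstream of the gene on the other strand, and strands were counted apart, so they are not extensions of these genes. A hypothesis is that they may share the control of the genes beside them.

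A second hypothesis, that a gene and its antisense transcripts change in opposite directions, was not borne out. Each gene with a tested antisense transcript was taken once per comparison with WT. Of 39 such pairs of gene and comparison with a called gene, 22 had the opposite sign (56.4%). This compares with 53.4% over all 2910 pairs and 28.2% to 76.9% in 1000 random draws. A gene called in several comparisons counts more than once, as YIL169C and HPF1 do in every comparison with WT.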
